A study of Mus musculus with 37 samples.

How the data were processed

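RNA was measured in 16 libraries of bone marrow-derived macrophages and 21 libraries of fibroblasts, each group and replicate being taken from the sample labels. Per the labels' protocols, cells were sorted live by F4/80 and CD11b, mRNA was captured on oligo-dT beads and libraries were prepared from 3′ ends by a massively parallel single-cell RNA-seq method applied to bulk samples. Reads were demultiplexed with bcl2fastq and aligned with STAR 2.4.2a to the mouse build mm10, and HTSeq is named among the tools, per the submitters' processing notes; the versions of bcl2fastq and HTSeq, the annotation, the use of strand and any treatment of molecular identifiers are not given in the sources used here. The deposited raw counts per gene are whole numbers, 1 table per cell type, with 11965 genes for macrophages and 14028 for fibroblasts. Every gene in them reaches 6 counts in at least 1 library, which points to a filter applied before deposit. The deposited normalised tables hold a signal that equals the raw count divided by 1 factor per library, the median-of-ratios size factor of DESeq2 (largest relative gap 5.33e-15). They served only to check the raw counts. Neither table holds rows without a gene name, and 0 columns were left without a sample or group.

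Because reads come from transcript 3′ ends, a gene's count does not scale with transcript length, and isoforms with different ends or genes that overlap at the 3′ end may be mixed. Genes with near-identical copies are likewise uncertain where counting split or dropped shared reads. Macrophages and fibroblasts were counted and tested in separate tables, so levels of the other cell type are set side by side only as CPM, counts scaled to the library total, within each table. The deposited counts had library totals of 3040103 to 7487355, at which 3 counts correspond to at most 0.987 CPM before TMM scaling. Intervals and floors of this kind cover counting error only, whereas the p-values measure the spread between libraries, which the labels describe as repetitions. Per the labels' protocols, cells of 2 females made up a biological replicate for mammary and fat fibroblasts. Pairs of libraries of 1 group differed by more than counting noise in all 54 pairs, with chi-square per degree of freedom of 3.47 to 72.2 over genes with a summed count of at least 20, so none was counted as a duplicate.

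The main test was edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood F-test with robust dispersion, TMM scaling and a filter on low counts (filterByExpr, minimum count 10). The 10295 macrophage genes and 12421 fibroblast genes that passed the filter were fitted in 1 model per table with a coefficient per group. A gene was called when its p, adjusted by the Benjamini-Hochberg method over the genes tested, was under 0.05, and every adjusted p of a single gene refers to this test unless DESeq2 is named. Log2 fold changes are given with standard errors, taken as the size of the change divided by the square root of its F statistic. CPM values are given with the SD over libraries. Differences between organs in the response to co-culture were tested as interaction contrasts. The square root of the common dispersion was 16.9% in macrophages and 29.1% in fibroblasts.

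Lists of genes for cell programmes and for markers of other cell types were fixed before the data were examined. Each list was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the programme lists of a comparison. A list with 1 direction in camera is compared with all other genes, whereas fry asks only whether its own genes move. Marker levels are means over genes of log2(CPM + 0.5), compared by exact two-sided permutation tests. The share of the other cell type in a co-cultured library was estimated as the median over its markers of the rise over the control, divided by their level in the co-cultured partner. A gene counts as rich in the other cell type when that level exceeds 5 times the mean of the control group.

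The rule for the genes named in the text was set before the data were examined, as were the groups, the tests and most alternatives. For each co-culture comparison it took called genes with a mean of at least 20 CPM and no overlap between the groups: the 6 higher genes with the largest change that were not rich in the other cell type, the 3 that were, and the 6 lowest. It added up to 3 called members per programme list with the smallest adjusted p and the most abundant member not called. For each other comparison it took the 4 highest and 4 lowest genes and up to 2 called members per list, without the overlap condition for interactions. Predicted genes and ribosomal and mitochondrial genes were left out, and 10 signalling genes and the 2 sort markers were added whatever their call. The text prints leading genes and members of the lists it describes. The result of 1 gene that the rule names is not reported here. Gene positions come from the GENCODE vM21 annotation of GRCm38, the assembly also called mm10.

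Alternatives were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, only the 2 groups compared, the replicate number as a block, leaving out genes rich in the other cell type, subtracting the estimated share of the other cell type, and leaving out each library in turn. Alternatives added after seeing the data left out mammary libraries that stood apart on the second principal component, or set the replicate number as a block within each organ. The replicate numbers come from the sample labels. In mammary fibroblasts the deviations of same-numbered libraries from their group means correlated in all 5 pairs (0.293 to 0.555), above the limit of 0.1, and the numbers were taken to pair the libraries. Elsewhere they were not. A lung mono-culture library, number 3, has a title that names lung and a source label that names the mammary fat pad; it was kept with lung. In the fat mono-cultures 1 column carries a number that no title has, so that library stayed in its group without a number.

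The tests were run on simulated data, drawn from the means and sizes of the real libraries with known changes in 200 genes. In macrophages from fat co-culture against day 0 (10146 genes), 74.7% of 2-fold and 89.9% of 4-fold changes were recovered, and in mammary fibroblasts (12100 genes) 54.6% and 83.0%. In lung fibroblasts (12104 genes) 32.3% and 77.6% were recovered, and for the difference in response between lung and mammary fibroblasts (12131 genes) 12.0% and 57.6%. No simulated change was called with the wrong sign.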

Results

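Gene expression was measured by bulk sequencing of the 3′ ends of polyadenylated RNA in fibroblasts and macrophages from BALB/c mice aged 8 weeks, grown separately or together. Fibroblasts were expanded from mesometrial fat, lung and the mammary fat pad and depleted of cells carrying EpCAM, an epithelial surface protein, or CD45, a leukocyte surface protein. Macrophages were differentiated from bone marrow with conditioned medium of L929 cells, a line that secretes the macrophage growth factor CSF1. Co-cultures and fibroblast mono-cultures ran for 7 days, and control macrophages were collected at day 0. Live macrophages were taken as positive, and live fibroblasts as negative, for F4/80 and CD11b, a pair of macrophage surface proteins. The 16 macrophage libraries comprised 4 each from day 0, fat co-culture, lung co-culture and mammary co-culture. The 21 fibroblast libraries comprised 3 co-cultures and 2 mono-cultures of fat, 3 and 3 of lung, and 5 and 5 of mammary fibroblasts. Library totals ran from 3040103 to 6223115 counts in macrophages and from 3304605 to 7487355 in fibroblasts. A count of 3 corresponds to 0.482 to 0.987 CPM, the count scaled to the library total, in a macrophage library. The comparisons ask how each cell type differs after co-culture, and whether organs differ in that response.

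Each sorted population also held transcripts typical of its partner, and their levels moved with co-culture. In macrophages, 14 fibroblast markers such as collagen genes and Dcn averaged 3.33 ± 0.39 log2 CPM after fat co-culture, 2.55 ± 0.36 after lung and 4.09 ± 0.16 after mammary co-culture. At day 0 they averaged -0.01 ± 0.26 (SD, n = 4 each). Each organ exceeded day 0 in an exact two-sided permutation test (p = 0.0286, the smallest p that 4 against 4 libraries allow). In fibroblasts, 16 macrophage markers such as Lyz2 and Cd68 averaged 4.88 ± 0.78 log2 CPM in mammary co-cultures and 1.32 ± 1.59 in mono-cultures (SD, n = 5 each, exact permutation p = 0.0159). That permutation exchanged libraries without keeping same-numbered mammary libraries paired, and 5 pairs are too few for a two-sided exact p under 0.05. In lung the macrophage markers averaged 6.16 ± 0.20 against 3.39 ± 0.83 (n = 3 each, exact permutation p = 0.1, the smallest possible). In fat the means were 5.33 ± 1.19 and 3.43 ± 0.22 (n = 3 and 2, exact permutation p = 0.2, where the smallest possible is 0.1). Relative to the partner's own level, the markers corresponded to 1.73% ± 1.91 (fat, n = 3; 0.635% without co-culture library 1), 2.72% ± 0.59 (lung, n = 3) and 1.33% ± 0.89 (mammary, SD, n = 5) in co-cultured fibroblasts. These SDs cover libraries and not the disagreement between markers. In lung co-culture library 1, for example, single markers gave -13.4% to 9.35%, with quartiles of 1.46% and 3.44%. In co-cultured macrophages the shares were 1.34% ± 0.31, 0.792% ± 0.387 and 0.882% ± 0.101 (n = 4 each). In mammary mono-culture library 1 the macrophage markers averaged 4.13 log2 CPM, against at most 1.09 in the other 4, and without it the difference between mammary co-cultures and mono-cultures was 4.27 instead of 3.57. A gene is called fibroblast-rich or macrophage-rich here when its mean level in the co-cultured partner exceeded 5 times its mean in the control group.

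**Figure D1:**
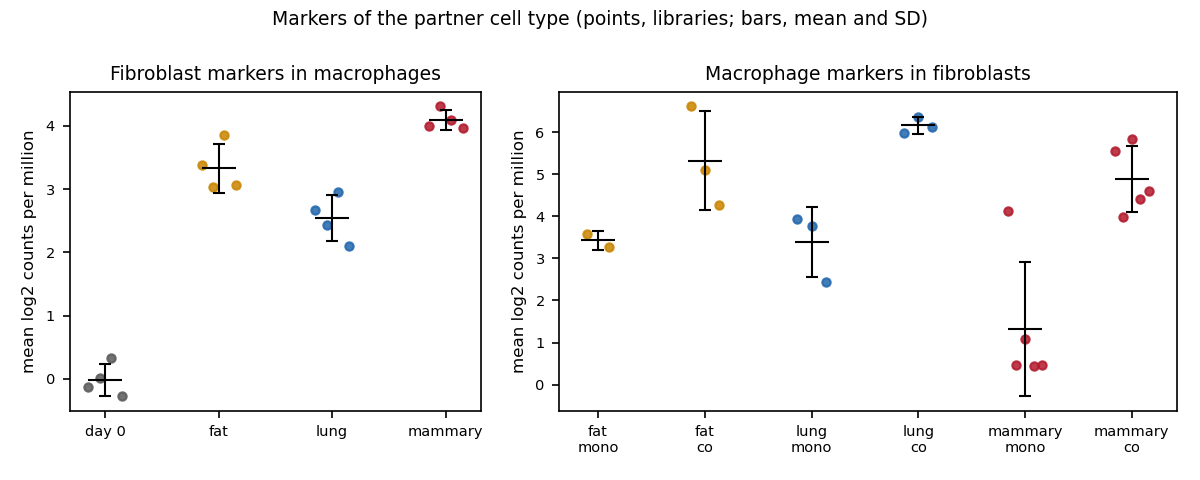
Mean log2 CPM of 14 fibroblast markers in each macrophage library (left) and of 16 macrophage markers in each fibroblast library (right), with points for libraries and bars for the mean and SD of a group. Fibroblast markers lay between -0.27 and 0.33 at day 0 and between 2.11 and 4.31 after co-culture.

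Macrophages from all 3 co-cultures expressed more Arg1 (chromosome 10, 24915221 to 24927484 of the mouse build GRCm38), the arginase of alternatively activated macrophages, than day-0 macrophages. Arg1 stood at 278 ± 155 CPM after fat, 131 ± 77.6 after lung and 240 ± 257 after mammary co-culture, against 6.14 ± 2.89 at day 0 (SD, n = 4 each; adjusted p = 0.00104, 0.00450 and 0.00147). Its log2 fold change in mammary co-culture was 5.27, or 4.27 without mammary library 1. F13a1, which encodes the A subunit of a clotting transglutaminase, rose from 8.28 ± 3.71 CPM to 115 ± 24.9, 153 ± 67.7 and 244 ± 68.5 (adjusted p = 2.80e-06, 1.22e-06 and 2.95e-07). Nxpe5 rose by 3.98 ± 0.19, 4.44 ± 0.19 and 4.08 ± 0.19 on the log2 scale (SE). Il1b, an inflammatory cytokine, rose from 4.58 ± 1.5 CPM to 105 ± 21.4 in fat and 94.9 ± 39.3 in lung co-culture (SD, n = 4 each; adjusted p = 5.96e-08 and 9.89e-08). Among the leading genes of single organs were Trem1, a receptor that amplifies inflammatory signalling, in fat (log2 fold change 5.04 ± 0.38), the endothelin receptor gene Ednrb in lung (5.89 ± 0.28) and the monocyte-attracting chemokine gene Ccl12 in mammary co-culture (4.53 ± 0.31).

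The cell-cycle inhibitor gene Cdkn1c fell from 40.2 ± 9.58 CPM at day 0 to 2.05 ± 1.19 after fat, 2.10 ± 0.353 after lung and 0.966 ± 0.399 after mammary co-culture (SD, n = 4 each; adjusted p = 2.03e-09, 2.73e-09 and 2.48e-10). The integrin gene Itgb7 changed by -3.19, -4.19 and -3.99 in fat, lung and mammary co-culture, and Pparg, a nuclear receptor of lipid metabolism, by -3.18, -2.38 and -3.43. Class II genes, whose products present antigen to T cells, were led by H2-Aa at -3.36 ± 0.63, -4.75 ± 0.68 and -3.28 ± 0.63 (adjusted p = 0.00130, 0.000178 and 0.00165). Of 10 measured class II presentation genes, 5, 8 and 6 fell in fat, lung and mammary co-culture, the same counts adjusted over the list alone. Another 1, 1 and 2 rose, Cd86 among them in fat and mammary co-culture (3.23 and 3.64). Counts of Cd86 were near the floor, with sums over 4 libraries of 6 at day 0, 60 in fat and 97 in mammary co-culture. The list passed the camera test in all 3 (adjusted p = 0.0321, 3.22e-05 and 0.0405), and with an estimated correlation the adjusted p was 0.248, 0.0348 and 0.284. Without fibroblast-rich genes the camera adjusted p in mammary co-culture was 0.0656.

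Interferon-stimulated genes were lower in every co-culture. Of 27 measured members, 22 fell in fat, 23 in lung and 21 in mammary co-culture (23, 24 and 22 adjusted over the list alone) and 0 rose. Median log2 changes were -1.77, -2.06 and -1.48 (camera adjusted p = 1.93e-15, 4.44e-18 and 3.43e-12). With an estimated correlation the adjusted p was 0.0234, 0.0202 and 0.0467, the last 0.0831 without fibroblast-rich genes. Ifit3, which restrains viral translation, changed by -2.73 ± 0.22, -3.14 ± 0.23 and -2.17 ± 0.21, and the transcription factor gene Irf7 by -2.08, -2.39 and -1.70. Ifitm3, an abundant member, stayed uncalled at 563 ± 65.0, 670 ± 171 and 648 ± 40.1 CPM against 645 ± 49.8 at day 0 (SD, n = 4 each).

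Genes of glycolysis and the hypoxia response were higher after co-culture. Of 22 measured, 15, 16 and 16 rose in fat, lung and mammary co-culture (17, 18 and 18 adjusted over the list alone), of which 5, 6 and 7 were fibroblast-rich. The camera adjusted p was 8.12e-10, 1.28e-10 and 2.60e-12, or 0.00503, 0.00373 and 0.00279 with an estimated correlation. The glucose transporter gene Slc2a1 rose 4.29-fold, 4.01-fold and 4.21-fold. The lactate transporter gene Slc16a3, fibroblast-rich in each organ, rose 5.36-fold, 4.80-fold and 6.94-fold. Pkm, which makes pyruvate, was uncalled at 2627 ± 140 CPM in lung and 2488 ± 382 in mammary co-culture against 3066 ± 453 at day 0 (SD, n = 4 each).

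Inflammatory cytokine and chemokine genes rose in 10, 13 and 10 of 18 cases, of which 4, 3 and 4 were fibroblast-rich, and fell in 1, 3 and 0. The camera adjusted p was 1.40e-06, 1.32e-08 and 1.39e-07 (0.0162, 0.00729 and 0.00944 with an estimated correlation). Without fibroblast-rich genes the adjusted p with an estimated correlation was 0.0517 in fat and 0.0708 in mammary co-culture. Adjusted over the list alone, 10, 13 and 12 rose. Cxcl1, a neutrophil-attracting chemokine gene, rose 7.14-fold in fat and 5.55-fold in lung co-culture. The fibroblast-rich feedback inhibitor gene Socs3 rose by 4.00, 4.01 and 4.07 on the log2 scale. Receptors of phagocytosis and complement shifted upward. The inhibitory Fc receptor gene Fcgr2b rose by 3.43, 3.69 and 3.96 on the log2 scale and C1qb, a chain of complement C1q, by 3.07, 2.94 and 3.15. Of 17 measured members, 11, 9 and 10 rose and 3, 3 and 2 fell, the same counts adjusted over the list alone. Their camera adjusted p was 7.63e-06, 0.000185 and 0.000157, and the adjusted p was 0.0480, 0.0839 and 0.0937 with an estimated correlation. Genes of alternative activation rose in 10, 10 and 9 of 14 cases (10, 11 and 9 adjusted over the list alone) and fell in 2, 0 and 4. Here the camera adjusted p was 0.000105, 1.95e-07 and 0.000353, or 0.00503, 0.00207 and 0.00696 with an estimated correlation. The transglutaminase gene Tgm2 rose 6.50-fold, 4.52-fold and 4.38-fold. Mrc1, the mannose receptor, rose 5.19-fold in lung and 4.31-fold in mammary co-culture.

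Genes of lipid handling and the lysosome went both ways: 5, 8 and 4 of 24 rose and 10, 9 and 10 fell (camera adjusted p = 0.173, 0.884 and 0.0518). Adjusted over the list alone, 7, 9 and 5 rose. Spp1, the secreted phosphoprotein osteopontin, rose from 1911 ± 338 CPM to 10764 ± 2530, 10794 ± 1423 and 12246 ± 2488 (SD, n = 4 each; adjusted p = 4.27e-09, 5.23e-09 and 1.96e-09). The lipoprotein lipase gene Lpl changed by -2.93 ± 0.40 in fat and -4.09 ± 0.43 in mammary co-culture, while Apoe, an apolipoprotein gene, rose by 2.30 and 2.11. Cholesterol synthesis genes rose in 10, 17 and 8 of 21 cases (12, 19 and 9 adjusted over the list alone), with 0 lower. Their list had a camera adjusted p of 0.000191, 9.29e-09 and 0.00135, and the adjusted p was 0.237, 0.0577 and 0.304 with an estimated correlation. Cell-cycle genes fell in 9, 10 and 11 of 32 cases (9, 11 and 12 adjusted over the list alone), among them the replication licensing gene Mcm6 at -1.33, -1.19 and -1.09. The cell-cycle list had a camera adjusted p of 0.00202, 0.000423 and 0.000475, but the adjusted p was 0.487, 0.374 and 0.414 with an estimated correlation.

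Collagen genes, all fibroblast-rich where called higher, were detected at higher levels in co-cultured macrophages. Of 14 collagen genes, 12, 11 and 13 rose in fat, lung and mammary co-culture, of which 12, 11 and 13 were fibroblast-rich, and 1 fell in each. These counts were the same adjusted over the list alone (camera adjusted p = 2.21e-09, 7.77e-06 and 3.43e-12). After subtraction of the estimated fibroblast share the list no longer passed in fat (camera adjusted p = 0.622, downward) or lung (0.107, downward), and passed upward in mammary co-culture (0.0126). The directional fry test then gave adjusted p = 0.693 (upward), 0.000369 (downward) and 1.74e-06 (upward). Col1a2 reached 70.0 ± 16.8, 45.7 ± 16.2 and 136 ± 8.82 CPM against 1.69 ± 1.02 at day 0 (SD, n = 4 each), beside the fibroblast marker levels given above. Col18a1, the exception, changed by -1.78 in fat and -2.08 in lung co-culture.

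Among genes of signalling between the 2 cell types, Csf1r, the receptor for the growth factor CSF1, was uncalled in macrophages at 1846 ± 305, 1578 ± 182 and 1526 ± 282 CPM against 1607 ± 224 at day 0 (SD, n = 4 each). Pdgfb, a growth factor for fibroblasts, changed by -0.90 ± 0.22, -0.97 ± 0.22 and -0.72 ± 0.22 after fat, lung and mammary co-culture (adjusted p = 0.00401, 0.00253 and 0.0180). In mammary co-culture its adjusted p was 0.0502 without day-0 library 4 and 0.0561 without mammary library 1. Its relative Pdgfa rose in fat and mammary co-culture (0.87 and 0.54; adjusted p = 5.64e-05 and 0.00540) and was uncalled in lung (-0.37; adjusted p = 0.0510). Csf1 and the protease inhibitor gene Timp1, both fibroblast-rich, rose by 2.28, 1.95 and 2.81 and by 3.30, 3.13 and 3.71. Cd63, which encodes a receptor for TIMP1, was uncalled at -0.34, -0.02 and -0.05. Of the sort markers, Itgam (CD11b) rose by 0.68, 0.67 and 0.60, and Adgre1 (F4/80) was uncalled at 0.31, 0.12 and 0.12. The circuit list as a whole had 15, 11 and 13 of 23 members higher and 2, 3 and 2 lower; adjusted over the list alone, 15, 12 and 13 were higher. The camera adjusted p was 4.57e-07, 4.07e-05 and 1.5e-06, or 0.00883, 0.0274 and 0.010 with an estimated correlation. Without fibroblast-rich genes the adjusted p was 0.158, 0.370 and 0.236 with an estimated correlation, and by camera with the preset correlation 0.0596 in lung co-culture. After subtraction of the fibroblast share the adjusted p was 0.0727 in lung co-culture with an estimated correlation.

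Of 10295 genes tested, 3106 passed an adjusted p of 0.05 in fat co-culture (1623 higher, 1483 lower), 2857 in lung (1499 and 1358) and 2690 in mammary co-culture (1479 and 1211). Of the higher genes 402, 374 and 388 were fibroblast-rich. In all 3 organs 939 genes were higher and 771 lower, where independent lists of these sizes would share 34.0 and 23.0. Because the 3 comparisons use the same day-0 libraries, 20 simulations were run with every library, day 0 included, drawn from the day-0 means. On average 0.0333 genes were called per comparison, and the largest number called the same way in all 3 was 0. With so few calls, the simulations cannot show how far shared day-0 noise raises the overlap of called genes. Fold changes across genes correlated between organs with r = 0.866 to 0.910 (simulated mean 0.507) and covariances of 0.714 to 0.770 (simulated mean 0.0312). With the day-0 libraries divided between the 2 organs compared, pairs of organs shared 704 to 809 higher genes, where independent lists would share 121 to 143. They shared 483 to 575 lower genes, where 69.8 to 87.3 would be shared, and r was 0.773 to 0.83. Genes are not independent replicates, so these correlations carry no p-value. Time in culture differs along with co-culture in these comparisons, since day-0 macrophages were not kept for the 7 days.

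**Figure D2:**
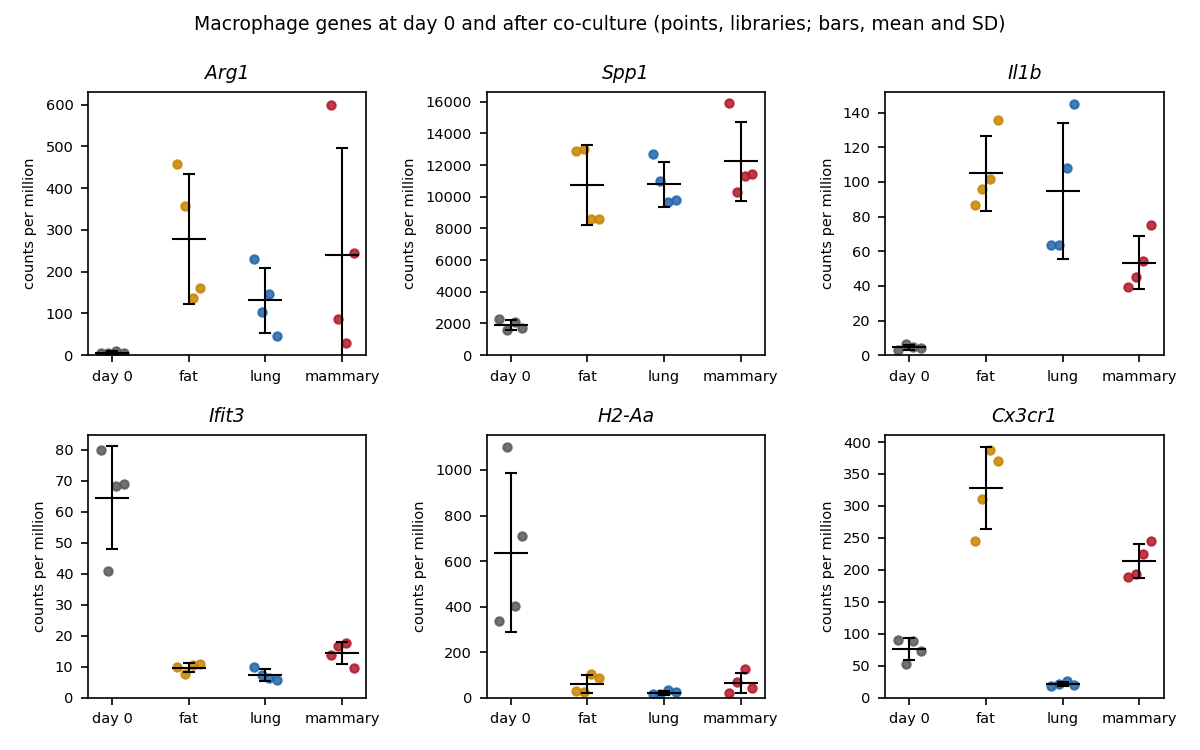
CPM of 6 macrophage genes in the 4 libraries of each group, on linear axes that start at 0, with points for libraries and bars for the mean and SD. Spp1 rose from 1911 ± 338 CPM at day 0 to 10764 ± 2530 or more in each co-culture, and Cx3cr1 stood at 21.6 ± 3.60 after lung against 328 ± 64.2 after fat co-culture.

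Co-cultured macrophages also differed by the organ of their partner fibroblasts. The fractalkine receptor gene Cx3cr1 (chromosome 9, 119901616 to 120069879) stood at 328 ± 64.2 CPM after fat and 21.6 ± 3.60 after lung co-culture (SD, n = 4 each; adjusted p = 8.91e-11). After mammary co-culture it stood at 214 ± 26.5 (adjusted p = 1.40e-09 against lung). Olfml3 differed alike, by 3.25 ± 0.18 between fat and lung and -3.02 ± 0.18 between lung and mammary co-culture. Lung co-culture gave the highest Ednrb, with log2 differences of -2.99 (fat minus lung) and 3.80 (lung minus mammary), and more Cd5l, a secreted macrophage scavenger protein gene (-1.90 and 2.31). The chemokine gene Ccl8 was lower after fat than after lung (-3.46) and mammary co-culture (-2.87). Tspoap1 was lower after mammary co-culture than after fat (3.48) and lung (3.81). Class II genes were lower after lung co-culture: 3 of 10 members differed from fat and 3 from mammary, also adjusted over the list alone. The camera adjusted p was 1.13e-06 and 2.47e-06 (0.0445 and 0.0430 with an estimated correlation).

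Immediate early and heat shock genes, which respond quickly to stress, were higher after fat and lung than after mammary co-culture. Of 22 measured, 15 were higher in fat and 12 in lung (16 and 14 adjusted over the list alone), with 0 lower (camera adjusted p = 8.97e-22 and 5.31e-13; 0.00755 and 0.0277 with an estimated correlation). Dusp1, a phosphatase that limits stress kinases, differed by 2.01 ± 0.17 and 1.93 ± 0.17, Atf3 by 1.67 and 1.80, and Egr1 by 2.15 between fat and mammary co-culture. Of the 4 mammary libraries 2, numbers 3 and 4, stood apart on the second principal component at 43.7 and 49.0 where the other 14 libraries lay between -22.4 and 12.2. Interferon genes were lower after lung than after mammary co-culture in 7 of 27 cases (12 adjusted over the list alone; camera adjusted p = 2.49e-07; adjusted p = 0.169 with an estimated correlation). Fibroblast transcripts in these macrophages differed too. Fibroblast markers were lower after lung than after mammary co-culture in 10 of 13 cases (camera adjusted p = 1.97e-15; 0.0139 with an estimated correlation), as were 10 of 14 collagen genes (camera adjusted p = 2.96e-11). In total 319 genes differed between fat and lung (212 higher in fat), 280 between fat and mammary (172 higher in fat) and 576 between lung and mammary co-culture (252 higher in lung). The fat and mammary count was 150 without mammary libraries 3 and 4, a choice made after seeing the data. It was 149, 184, 145 and 159 without fat library 1, fat 3, fat 4 or mammary 3, and the lung and mammary count was 339 without lung library 4.

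Fat fibroblasts expressed more Mgarp (chromosome 3, 51388412 to 51396738), a mitochondrial protein gene induced by low oxygen, in co-culture than alone, at 46.3 ± 4.00 CPM (SD, n = 3) against 12.2 ± 3.55 (n = 2; log2 fold change 1.92 ± 0.28 SE, adjusted p = 0.0168). Egln3, a prolyl hydroxylase that senses oxygen, and Cd248, the stromal glycoprotein endosialin, rose by 1.55 ± 0.27 and 1.47 ± 0.25 (adjusted p = 0.0199 and 0.0199). The transcription factor gene Klf2, which is macrophage-rich, rose by 1.69. Cdo1, which degrades cysteine, changed by -2.48 ± 0.41, the creatine transporter gene Slc6a8 by -1.33 ± 0.21, Atp6v1b2, a subunit of the lysosomal proton pump, by -1.15 ± 0.19, and Pparg by -2.17 ± 0.40. Without the fat mono-culture library that has no number, the change of Cdo1 was -1.77 and that of Pparg -1.23 (adjusted p = 0.308 and 0.510), and without mono-culture library 1 Pparg stood at -2.76. Of the 22 glycolysis and hypoxia genes 1 rose (4 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 3.75e-07; 0.00234 with an estimated correlation). Of 21 inflammatory cytokine genes 0 rose (5 adjusted over the list alone; median 1.25; camera adjusted p = 2.20e-06; 0.00234 with an estimated correlation). This list averaged 5.15 ± 0.17 log2 CPM in macrophages of fat co-culture (n = 4) and 2.43 ± 0.05 in fat mono-cultures (SD, n = 2). Macrophage RNA in the co-cultured fibroblasts could therefore add to its rise. Endothelial markers were lower, with 1 of 10 called (5 adjusted over the list alone; median -1.69; camera adjusted p = 4.03e-07; adjusted p = 0.112 with an estimated correlation). In total 25 of 12421 genes passed the test (5 higher, 20 lower), and 1228 had an unadjusted p under 0.05. With the replicate number as a block 0 genes passed, and 3 passed with the block within the organ. With edgeR the count was 0 when only the 2 groups were fitted or when fat co-culture library 1 or the fat mono-culture library without a number was left out. It was 2, 6 and 7 without co-culture library 2, co-culture 3 or mono-culture 1, and DESeq2 called 137 with all libraries. At these group sizes, simulated 2-fold changes were recovered in 25.8% of cases and 4-fold changes in 62.2%.

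Lung fibroblasts in co-culture showed the same direction for oxygen-related genes, with more members called. Ndufa4l2, which dampens mitochondrial respiration in low oxygen, stood at 183 ± 37.8 CPM against 25.6 ± 14.9 alone (SD, n = 3 each; adjusted p = 0.00122), a log2 fold change of 2.83, or 3.42 without mono-culture library 2. Mgarp, Slc16a3, the angiogenic factor gene Vegfa and Slc2a1 rose by 2.42 ± 0.25, 2.29 ± 0.22, 1.94 ± 0.28 and 1.5 ± 0.20. Of the 22 glycolysis and hypoxia genes 9 rose (17 adjusted over the list alone) and 1 of these was macrophage-rich. Their median was 1.03 (camera adjusted p = 2.85e-27; 7.85e-07 with an estimated correlation). The growth factor gene Fgf1 fell by 2.43 ± 0.42 on the log2 scale, with an adjusted p of 0.00419, or 0.0528 without mono-culture library 3. The serine protease inhibitor gene Serpina3g rose by 2.24 ± 0.35. Macrophage-rich genes made up part of the higher genes, among them the chemokine gene Cxcl14 (3.37 ± 0.37) and Fcer1g, an Fc receptor subunit gene (3.46 ± 0.77; its adjusted p reached 0.183 with 1 library left out). Of 16 macrophage markers 3 rose (12 adjusted over the list alone). In total 163 genes passed (145 higher, 51 of them macrophage-rich, and 18 lower). The count was 83 without macrophage-rich genes, 311 with DESeq2, 378 with only the 2 groups fitted, and 92, 80, 86, 65 and 60 without co-culture library 1, 2 or 3 or mono-culture library 1 or 3. Placing mono-culture library 3 in the mammary group, where 1 of its labels puts it, left 0. Its log2 levels correlated across genes with the mean of the other lung mono-cultures at r = 0.975 and with mammary mono-cultures at 0.83. On the first principal component it lay at -84.7, beside the other lung mono-cultures at -77.1 and -75.1. Mammary mono-cultures lay between 44.4 and 82.3. These values argue against the mammary label for this library.

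Mammary fibroblasts raised Rarres2 (chromosome 6, 48569696 to 48572789), which encodes the chemoattractant chemerin, from 398 ± 136 CPM alone to 2465 ± 982 in co-culture (SD, n = 5 each; adjusted p = 0.000868). Vwa1, a matrix protein gene, Cox4i2, an oxygen-regulated subunit of cytochrome c oxidase, and Dio3, which inactivates thyroid hormone, rose by 2.39 ± 0.28, 2.32 ± 0.35 and 2.27 ± 0.31. The calcification inhibitor Mgp changed from 854 ± 310 to 160 ± 126 CPM (adjusted p = 0.00204; log2 fold change -2.41, or -3.02 without co-culture library 1), the BMP antagonist Grem1 by -2.23 ± 0.46 and Lmcd1 by -1.87 ± 0.23. Of the 22 glycolysis and hypoxia genes 3 rose (6 adjusted over the list alone), namely Egln3 (1.02), Slc16a3 (0.61) and the pyruvate dehydrogenase kinase gene Pdk1 (0.88). The adjusted p of Slc16a3 and Pdk1 reached 0.107 and 0.120 with 1 library left out. The list's camera adjusted p was 3.66e-05 (0.00762 with an estimated correlation, or adjusted p = 0.170 when libraries of 1 number were also paired). Of 19 collagen genes 4 rose (7 adjusted over the list alone), including Col1a1 (0.80; adjusted p = 0.0604 without mono-culture library 3). The collagen list had a camera adjusted p of 0.00611 and an adjusted p of 0.297 with an estimated correlation. Inflammatory cytokine genes rose in 6 of 21 cases, 5 of them macrophage-rich, such as Saa3 (2.57 ± 0.47), and 1 fell. Adjusted over the list alone 9 rose (camera adjusted p = 3.66e-05; 0.00762 with an estimated correlation). Without macrophage-rich genes the list's camera adjusted p was 0.559, and with libraries of 1 number paired it was 0.112 with an estimated correlation. Phagocytosis and complement receptor genes rose in 5 of 16 cases, all 5 macrophage-rich (12 adjusted over the list alone; camera adjusted p = 6.54e-11; adjusted p = 0.174 with an estimated correlation, and 0.715 by camera after subtraction of the macrophage share). Macrophage markers rose in 8 of 16 cases, with Csf1r at 2.47 ± 0.50. In total 453 genes passed (293 higher, 105 of them macrophage-rich, and 160 lower), or 856 with the replicate number as a block within the organ, given because the mammary numbers paired the libraries. The count was 292 without macrophage-rich genes, 736 with DESeq2, 146 with only the 2 groups fitted, and 282, 265 and 273 without mono-culture library 2, 4 or 5. Placing lung mono-culture library 3 in the mammary group gave 254, with Saa3 at -3.79 (adjusted p = 0.239) and an adjusted p of 0.112 for Col1a1 and 0.177 for Slc16a3. It was 143 without the 4 libraries numbered 2 and 4, a choice made after seeing the data because co-culture libraries 2 and 4 stood apart on the second principal component.

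In fibroblasts of all 3 organs 2 genes were higher, Mgarp and Egln3, and 1 was lower, Atp6v1b2, which fell by 1.15 in fat, by 0.94 in lung and by 0.70 in mammary fibroblasts on the log2 scale. These 3 genes were named after the overlap was seen. The count of 3 was 0 without fat co-culture library 1, without fat mono-culture library 1, without the fat mono-culture library that has no number, and with the replicate block, and 29 with DESeq2. Lung and mammary fibroblasts shared 56 higher genes, where independent lists would share 3.42, and 5 lower genes, where 0.232 would be shared. Their fold changes correlated at r = 0.452 across genes. Both the overlap and this correlation include macrophage-rich genes, which were 51 of 145 higher genes in lung and 105 of 293 in mammary fibroblasts. Macrophage RNA carried through both sorts could raise the same genes, which independent lists do not allow for. Tested directly, the response differed between lung and mammary fibroblasts for 12 genes. The change with co-culture was higher in lung than in mammary fibroblasts by 3.45 ± 0.43 for Cxcl14, 2.42 ± 0.36 for Lmcd1 and 1.69 ± 0.27 for Slc16a3 on the log2 scale (SE; adjusted p = 0.00264, 0.00613 and 0.010). Grem1 (4.07 ± 0.72) and Cd14, an endotoxin co-receptor gene of macrophages and the 1 lower gene (-2.44 ± 0.43), passed as well, with adjusted p reaching 0.151 and 0.139 when 1 library was left out. The Grem1 difference was 4.73 without lung mono-culture library 2. With lung mono-culture library 3 placed in the mammary group 0 genes differed between lung and mammary, and Cd14 stood at 0.12. The glycolysis and hypoxia response was stronger in lung than in mammary fibroblasts (median difference 0.57; camera adjusted p = 2.12e-11; 0.000190 with an estimated correlation) and than in fat fibroblasts (fat minus lung -0.46; 8.59e-06; 0.00649 with an estimated correlation). Between fat and mammary fibroblasts 3 genes differed, Trp53i11 (-2.92 ± 0.43, with an adjusted p up to 0.0911 when 1 library was left out and 0.987 with lung mono-culture library 3 placed in the mammary group) and 2 endothelial genes named after their values were seen. Dll4, a Notch ligand gene, stood at 10.3 ± 5.93 CPM in fat mono-cultures (n = 2), 0.942 ± 0.366 in fat co-cultures (n = 3), 0.831 ± 0.475 in mammary co-cultures and 0.0447 ± 0.10 in mammary mono-cultures (SD, n = 5 each). The receptor gene Tie1 stood at 10.1 ± 2.11, 1.02 ± 0.299, 0.628 ± 0.388 and 0.0447 ± 0.10 CPM in the same order. Of 10 endothelial markers 7 differed alike adjusted over the list alone and 1 over all genes (median -2.51; camera adjusted p = 3.57e-11; 0.0204 with an estimated correlation). The markers averaged 4.12 ± 0.63 log2 CPM in fat mono-cultures and 2.50 ± 0.67 in fat co-cultures. In mammary mono-cultures and co-cultures they averaged 0.64 ± 0.53 and 1.52 ± 0.60 (SD). The differences in these endothelial genes therefore cannot be assigned to the fibroblasts themselves. Between fat and lung fibroblasts edgeR called 0 genes, with 813 at an unadjusted p under 0.05, and DESeq2 called 46. The lung and mammary count was 6, 6, 7 and 6 without lung co-culture library 1, lung mono-culture 3, mammary co-culture 1 or mammary mono-culture 2, 63 with the block within the organ, 22 with the block on the number alone and 52 with DESeq2. Without the mammary libraries numbered 2 and 4 the lung and mammary count was 7 and the fat and mammary count 0. The fat and mammary count was 0, 1, 0, 1, 8, 0, 0 and 0 without fat co-culture 1, fat co-culture 3, fat mono-culture 1, mammary co-culture 1, mammary co-culture 2, mammary mono-culture 2, mammary mono-culture 3 or mammary mono-culture 5. It was 0 with the block on the number alone, 0 with the block within the organ and 27 with DESeq2.

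**Figure D3:**
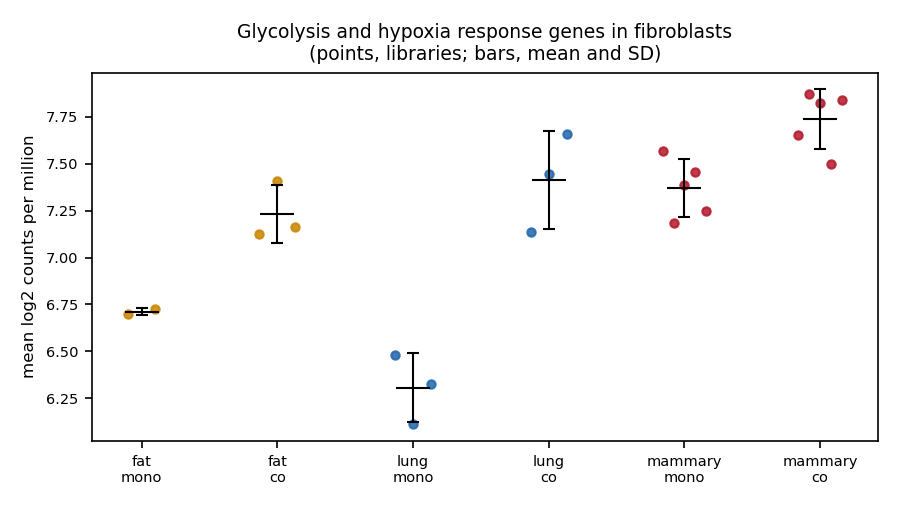
Mean log2 CPM of 22 glycolysis and hypoxia response genes in each fibroblast library, by organ and culture, with points for libraries and bars for the mean and SD of a group. The levels were 6.71 ± 0.02 alone and 7.23 ± 0.15 with macrophages in fat, 6.31 ± 0.18 and 7.41 ± 0.26 in lung, and 7.37 ± 0.15 and 7.74 ± 0.16 in mammary fibroblasts.

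Mono-cultured fibroblasts differed by organ in many genes, developmental regulators among them. Hoxc10 (chromosome 15, 102966796 to 102971893), a posterior Hox gene, stood at 95.3 ± 8.93 CPM in fat (SD, n = 2), 0.602 ± 0.243 in lung (n = 3) and 105 ± 19.3 in mammary fibroblasts (n = 5; adjusted p = 7.08e-11 for fat against lung and 7.59e-12 for lung against mammary). Gata6, a transcription factor gene of internal organs, was higher in fat (3.53 ± 0.20) and in lung (4.59 ± 0.19) than in mammary fibroblasts. With lung library 3 placed in the mammary group these differences were 1.39 and 2.53 (adjusted p = 0.407 and 0.0783). Tbx15, a limb and trunk patterning gene, was lower in fat than in mammary fibroblasts (-7.03 ± 0.45; -6.43 without fat library 1 and -7.87 without the fat library that has no number). Of 46 Hox and patterning genes, 17 were higher and 13 lower in fat than in lung (18 and 15 adjusted over the list alone), 16 and 10 in fat than in mammary (17 and 11), and 14 and 22 in lung than in mammary fibroblasts (14 and 22). Mixed directions left the list uncalled by camera (adjusted p = 0.175, 0.733 and 0.154), while fry's test of change in either direction gave 5.29e-18, 5.19e-19 and 6.54e-18.

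Mesothelial markers separated fat and lung from mammary mono-cultures. Msln (chromosome 17, 25748613 to 25754378), which encodes mesothelin, was higher in fat (448 ± 169 CPM, n = 2) than in mammary mono-cultures (1.34 ± 2.07, SD, n = 5; adjusted p = 6.89e-07). The log2 difference was 8.34, or 9.91 without mammary library 3, and 2.28 (adjusted p = 0.468) with lung library 3 placed in the mammary group. Of 9 measured mesothelial markers 8 were higher in fat and 8 in lung than in mammary fibroblasts, also adjusted over the list alone. The median log2 differences were 8.01 and 8.71 (camera adjusted p = 9.37e-08 and 6.68e-07; adjusted p = 0.0451 and 0.0782 with an estimated correlation). Of 6 epithelial markers, mostly keratins, 5 were higher in fat and 5 in lung than in mammary mono-cultures (camera adjusted p = 8.66e-06 and 2.21e-05; adjusted p = 0.0458 and 0.0782 with an estimated correlation). Endothelial markers were higher in fat than in mammary mono-cultures in 8 of 10 cases and than in lung in 6 (camera adjusted p = 1.05e-06 and 5.92e-07; adjusted p = 0.0451 and 0.106 with an estimated correlation). The other side of the contrast held fibroblast markers, lower in fat and lung than in mammary fibroblasts in 9 and 10 of 16 cases (camera adjusted p = 1.80e-05 and 0.000198; adjusted p = 0.0451 and 0.0782 with an estimated correlation). Col6a3, a collagen gene, differed by -3.88 ± 0.47 and -4.14 ± 0.40.

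Inflammatory and metabolic genes differed by organ as well. Saa3, an acute-phase gene, stood at 14290 ± 3858 CPM in lung (n = 3), 462 ± 1.01 in fat (n = 2) and 31.1 ± 16.6 in mammary mono-cultures (SD, n = 5; adjusted p = 5.29e-09 for lung against mammary). The complement gene C3 was higher in lung (7.90 ± 0.59) and fat (4.98 ± 0.56) than in mammary fibroblasts. These values changed when lung library 3 was placed in the mammary group. Moved to the mammary group, that library left C3 at 2.52 in lung and -0.39 in fat (adjusted p = 0.287 and 0.935). Saa3 in lung against mammary was then 2.45 (adjusted p = 0.344). Leaving the library out instead ended no call of C3 or Saa3 between lung and mammary mono-cultures. Its profile, as given above, correlated better with the other lung mono-cultures than with mammary mono-cultures. On the first principal component it also lay with lung, which argues against the mammary label. The changes after the move therefore come from a placement that the profile goes against. Of 11 complement genes 9 were higher in lung and 6 in fat than in mammary (10 and 7 adjusted over the list alone; camera adjusted p = 0.00128 and 0.0200; adjusted p = 0.535 and 0.662 with an estimated correlation). Glycolysis and hypoxia genes were lower in fat and in lung than in mammary mono-cultures, in 13 of 22 cases each (15 and 13 adjusted over the list alone; camera adjusted p = 2.52e-05 and 7.45e-06; 0.00952 and 0.00618 with an estimated correlation), with Vegfa at -1.68 and -2.56 (adjusted p = 0.122 in fat with lung library 3 moved). Genes of the unfolded protein response were lower in 7 and 11 of 20 cases (9 and 11 adjusted over the list alone; camera adjusted p = 0.00183 and 0.000570; adjusted p = 0.231 and 0.322 with an estimated correlation), with the stress factor gene Ddit3 at -2.32 and -2.40. Of the circuit genes, Csf1 was lower in lung than in mammary fibroblasts (-1.38 ± 0.24) and the EGF receptor gene Egfr was higher (1.40 ± 0.19), with adjusted p of 0.0752 and 0.0811 when lung library 3 was moved, whereas the PDGF receptor gene Pdgfra did not pass the test (0.11; adjusted p = 0.818).

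In total 1153 genes differed between fat and lung mono-cultures (681 higher in fat), 2896 between fat and mammary (1753 higher in fat) and 5010 between lung and mammary (2637 higher in lung). Moving lung library 3 to the mammary group gave 177, 729 and 825. Without fat library 1 or the fat library without a number, the fat and lung count was 757 and 427 and the fat and mammary count 1480 and 1916. With a block on the replicate number these counts were 453 and 1516.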

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

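The tests for mesothelial cells, for a technical axis shared by both tables, of partner-rich genes whether called or not, and of list calls and of the lung and mammary difference over splits that part the mammary pairs were chosen only after the result was seen, and the other tests in this part were set beforehand.

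Genes of the partner cell type rose in both sorted populations, and cells or RNA carried through the sort, which would raise each gene by about the share that the partner's markers give, are a candidate explanation. Among partner-rich genes where that share would add at least 1 CPM and the control level or more, taken whether called or not, 93.2% of 337 in lung and mammary fibroblasts and 83.3% of 420 in macrophages rose within 3 times of it, as carry-over would give. Among called genes 67.6% of 145 and 36.6% of 1126 lay within 3 times of it, but called genes were chosen for their rise and overstate it, so this comparison, set beforehand, decides nothing. Of the other 1814 fibroblast-rich cases in macrophages, 723 were called higher and 401 (22.1%) still were after 3 times the share had been subtracted, which argues against carry-over at that share as the whole cause for them; of the other 1027 macrophage-rich cases in fibroblasts 55 were called and 18 (1.75%) still were, too few calls to decide. Regulation within the cells, selective uptake of RNA and carried cells with another profile than the sorted partner stay open and were not tested.

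Mesothelial markers were high in fat and lung mono-cultures, and mesothelial cells in these cultures are a candidate source. Of 9 measured markers, 8 were called over 10 times higher than in mammary mono-cultures in both organs, the exception being Krt19, which is also an epithelial marker; Lrrn4 stood at 812 CPM in fat and 1023 in lung against 2.00 in mammary mono-cultures, and Upk1b at 506 and 728 against 1.70. The beads were directed at EpCAM and CD45 and the sort excluded cells with F4/80 or CD11b, none of which is a mesothelial marker in the list. Epithelial cells cannot be told apart from this, since of the pair of genes named for that test only 1, Krt18 at 86.3 and 172 CPM, was analysed here. Mesothelial genes expressed by fibroblasts of these organs stay open as a biological difference that was not tested.

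On the second principal component, which held 17.4% of the variance in macrophages and 13.9% in fibroblasts, mammary macrophage libraries 3 and 4 lay at 43.7 and 49.0 and mammary co-culture fibroblast libraries 2 and 4 at 65.2 and 98.4. If 1 technical axis ran through both tables, the genes behind the component would be alike. Their loadings correlated with a Spearman coefficient of 0.354 across 9856 genes, which are not independent. Any axis shared by both tables, technical or biological, would give alike loadings, so a technical axis stays possible but the value cannot single it out. Loadings correlated with the GC content of the 3′ ends of the transcripts at 0.141 in macrophages and 0.397 in fibroblasts, between the bounds set beforehand for the smaller of these, which keeps GC content open. No biological explanation was tested, since the labels give none for these libraries.

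In groups of 4 or 5 libraries, 13 of 191 gene levels had 1 library far from the others by Dixon's ratio of gap to range, where chance marks about 1 in 20. At day 0 these were Arg1 in library 3 (10.4 CPM against 4.34 to 5.21, ratio 0.858) and Irf7 in library 2 (419 against 743 to 761, ratio 0.949). After mammary co-culture macrophage library 3 was high for Cd86 (5.58 against 4.03 to 4.15, ratio 0.922) and library 4 low for Mcm6 (111 against 126 to 128, ratio 0.861). Macrophage library 1 of lung co-culture was high for Col18a1 (49.3 against 33.1 to 35.0, ratio 0.886), and library 2 of fat co-culture for Ednrb (61.4 against 46.9 to 49.2, ratio 0.837). Among mammary mono-cultures, library 1 was high for Csf1r (19.0 against 4.55 to 6.32, ratio 0.877) and Trp53i11 (12.3 against 5.65 to 6.99, ratio 0.798) and low for Rarres2 (161 against 407 to 494, ratio 0.739). Library 3 of that group was high for Egfr (87.8 against 51.7 to 61.1, ratio 0.739) and Msln (5.00 against 0 to 0.894, ratio 0.821), and library 4 low for C3 (5.10 against 16.6 to 19.6, ratio 0.792). Mammary co-culture library 1 was high for Mgp (378 against 58.0 to 143, ratio 0.735).

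Direct tests between organs gave 319 genes for macrophages of fat against lung co-culture, 280 for fat against mammary and 576 for lung against mammary. For the response of fibroblasts to co-culture they gave 3 genes for fat against mammary, with Trp53i11 at -2.92, and 12 for lung against mammary. The latter differences in log2 change were 3.45 for Cxcl14, 4.07 for Grem1, 2.42 for Lmcd1, 1.69 for Slc16a3 and -2.44 for Cd14. The median difference of glycolysis and hypoxia genes was -0.46 for fat minus lung and 0.57 for lung minus mammary.

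Other splits of the same libraries were fitted to see whether chance can be excluded as the source of each count. It can for macrophages of fat, lung and mammary co-culture against day 0, where 1 of 35 splits, the real one, reached the real 3106, 2857 and 2690 genes and the highest other gave 294, 292 and 1. It can also for the differences between co-cultures, with 1 of 35 splits each and 0, 55 and 88 as the highest other against 319, 280 and 576. The same holds for lung against mammary mono-cultures (1 of 56, highest other 2988 against 5010). For the 1710 genes called alike in all 3 organs only the real split of 100 reached the count (highest other 0). Those splits shuffled day-0 libraries with co-culture libraries, which removes the difference from day 0 itself. They therefore cannot show how far the shared day-0 libraries raise the overlap. For the 73 list calls in macrophages only the real split of 100 reached the total, but the highest other gave 66. This covers the total over all macrophage comparisons, and since shuffled libraries gave up to 66 list calls it excludes chance for no single list. In mammary fibroblasts 5 of 100 splits reached the real 453 genes, so chance cannot be excluded this way, and the highest other gave 2337. That split exchanged co-culture libraries 2 and 4 with mono-culture libraries 1 and 3, and a count several times the real one points to a structure of the samples. Among the 16 splits that part every numbered pair the real one was the highest and the highest other gave 0; 16 splits are too few for a share under 0.05. For the difference between lung and mammary fibroblasts 8 of 100 splits reached the real 12, with 201 as the highest other, again a sign of structure. Of 100 splits that also part every numbered mammary pair 6 reached it, with 644 as the highest other, so chance cannot be excluded for this count. The real 7 list calls in mammary fibroblasts were reached by 23 of 100 splits (highest other 12), so chance cannot be excluded there either. Among the 16 splits that part every numbered pair 4, the real one included, reached 7 list calls and the highest other gave 9; these are too few for a share under 0.05. In lung fibroblasts the 10 splits are too few, with 163 genes and a highest other of 0, and with 13 list calls and a highest other of 12.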

How the results depend on the processing

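The alternatives that left out mammary libraries apart on the second principal component, and the replicate block within each organ, were chosen only after the results were seen; the others were set beforehand. Counts for macrophages against day 0, and for lung against mammary mono-cultures except with lung library 3 moved, stayed within 1.5 times of those reported. The marker differences in macrophages and in mammary fibroblasts kept an exact p under 0.05 in each alternative, none of which kept the mammary pairs. Those in fat and lung fibroblasts could not reach such a p with so few libraries. With a pseudocount of 5 CPM they were 1.52, 1.07 and 2.06 instead of 3.35, 2.56 and 4.10 for fibroblast markers in macrophages, and 1.49, 2.14 and 2.12 instead of 1.90, 2.78 and 3.57 for macrophage markers in fibroblasts (fat, lung and mammary). The 160 pairs of gene and comparison in the text all kept direction and call with DESeq2 and with its size factors. Leaving out 1 library at a time gave 1301 values, of which 78 lost the call, 3 gained one and 0 reversed. Without a filter on low counts 1 lost and 1 gained the call, with only the 2 groups fitted 11 of 153 lost it, and with the replicate block 10 of 160 lost and 1 gained it. After subtraction of the other cell type 3 of 119 lost it, without genes rich in the other cell type 2 of 101, with the block within organ 9 of 36, and without mammary libraries 2 and 4 10 of 36. For counts that moved, the cause was not tested, except where fewer genes or libraries entered by construction. DESeq2 called 137, 311 and 736 genes in fat, lung and mammary fibroblasts, 46, 27 and 52 for the differences fat to lung, fat to mammary and lung to mammary, and 29 the same way in all 3 organs. The replicate block gave 0 in fat fibroblasts, 453 and 1516 for mono-cultures of fat against lung and mammary, 0 and 22 for the differences fat to mammary and lung to mammary, and 0 in all 3 organs; it moved no other count by more than 1.5 times. Numbers did not pair the other libraries: same-numbered deviations correlated at 0.0429 to 0.340 in lung, where each of 3 pairs was best with its own number, 0.0125 for the 1 fat pair, and -0.358 to 0.286 in macrophages. With only the 2 groups fitted the fibroblast counts were 0, 378 and 146. Without macrophage-rich genes lung gave 83 and mammary 292. Without macrophage libraries 3 and 4 of mammary co-culture, fat against mammary gave 150. Without the mammary libraries numbered 2 and 4 the count was 143 in mammary fibroblasts, and 0 and 7 for the differences fat to mammary and lung to mammary. The replicate block within organ gave 3, 367 and 856 in fat, lung and mammary fibroblasts, and 1, 0 and 63 for the differences fat to lung, fat to mammary and lung to mammary. With lung mono-culture library 3 placed in the mammary group, lung fibroblasts gave 0, mammary 254, mono-cultures 177 (fat to lung), 729 (fat to mammary) and 825 (lung to mammary), and the difference lung to mammary 0; of 46 gene values 24 lost the call and 3 reversed, namely Saa3 in mammary fibroblasts at -3.79, C3 in fat against mammary mono-cultures at -0.39 and Cd14 in the difference lung to mammary at 0.12. Placing that library in the mammary group goes against its profile, as given above. With an estimated correlation, list calls went from 73 to 44 in macrophages and from 59 to 11 in fibroblasts.

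Leaving out each library in turn gave 2547 to 3328, 2332 to 3087 and 2208 to 2880 genes against day 0 and 1399 to 1896 in all 3 organs. Between co-cultures it gave 226 to 297 for fat and lung, 145 (fat 4 out) to 364 (mammary 1 out) for fat and mammary, and 339 (lung 4 out) to 703 for lung and mammary. Fibroblast counts were 0 (fat co-culture 1 out) to 7 in fat, 60 (mono-culture 3 out) to 121 in lung and 265 (mono-culture 4 out) to 484 in mammary, 0 to 9, 0 to 8 and 6 to 15 for the differences fat to lung, fat to mammary and lung to mammary, and 0 to 4 in all 3 organs. Mono-cultures gave 427 to 907 for fat and lung, 1480 to 3078 for fat and mammary, and 4094 to 5077 for lung and mammary. A fat mono-culture left with 1 library is assumed to vary like the other groups. Rises of fibroblast markers were 3.17 to 3.46, 2.42 to 2.70 and 4.02 to 4.22 log2 CPM, and of macrophage markers 1.26 to 2.43, 2.30 to 3.06 and 3.33 to 4.27 in fat, lung and mammary co-culture. At the depth and group sizes of these libraries, simulated 2-fold changes were recovered in 25.8% of cases in fat and 32.3% in lung fibroblasts, so a gene without a call is not shown to be unchanged.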

Other observations

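The test of lysosomal genes was chosen only after the result was seen, and the test of hypoxia genes after subtraction was set beforehand.

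Complement component genes were higher in macrophages after co-culture, in 8, 9 and 7 of 9 measured cases for fat, lung and mammary partners (9, 9 and 7 adjusted over the list alone), of which 8, 8 and 6 were fibroblast-rich. The camera adjusted p was 1.40e-06, 2.65e-08 and 1.68e-06, or 0.00771, 0.00373 and 0.00710 with an estimated correlation. Without fibroblast-rich genes too few members were left to test the list in fat and lung co-culture. In mammary co-culture the camera adjusted p was then 0.0529. Genes of matrix proteases and their inhibitors rose in 13, 12 and 12 of 17 cases, 9, 8 and 9 of them fibroblast-rich, and fell in 2, 3 and 2 (camera adjusted p = 7.86e-07, 9.51e-07 and 5.21e-07; 0.00713, 0.00729 and 0.00696 with an estimated correlation). Without fibroblast-rich genes the camera adjusted p of that list was 0.329, 0.246 and 0.643. After subtraction of the fibroblast share its adjusted p was 0.126, 0.0682 and 0.0575 with an estimated correlation. Osteoclast markers went down, with 3, 3 and 4 of 5 lower and 1, 1 and 0 higher. Their median log2 changes were -1.80, -1.52 and -1.42 (camera adjusted p = 0.0226, 0.0423 and 0.00113; adjusted p = 0.260, 0.352 and 0.113 with an estimated correlation). In fibroblasts, contractile and TGF-beta target genes had medians of 0.59 in fat and 0.74 in lung co-culture with 0 of 22 called in each (camera adjusted p = 0.000539 and 9.23e-05; adjusted p = 0.370 and 0.206 with an estimated correlation), and 2 called higher in mammary co-culture at a median of -0.04 (camera adjusted p = 0.925).

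A hypothesis is that co-cultured fibroblasts themselves raise hypoxia-response genes. Macrophage RNA carried through the sort is a candidate explanation that the tables argue against: after subtraction of the estimated macrophage share, the largest fry adjusted p of the glycolysis and hypoxia list over the 3 organs was 0.000251. Oxygen levels in the wells were not analysed here.

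Another hypothesis is a fall of lysosomal genes as a group in co-cultured fibroblasts, raised by Atp6v1b2. Of 47 measured genes 46, 43 and 40 had a negative log2 fold change in fat, lung and mammary fibroblasts, with medians of -0.45, -0.32 and -0.44. Called lower were 5, 2 and 14 genes (15, 3 and 17 adjusted over the list alone), with fry adjusted p of 0.000816, 0.0178 and 0.000690 and a camera p of 0.00309, 0.0374 and 0.0146 with an estimated correlation. The list of lipid handling and lysosome genes fixed beforehand did not fall in every organ: of its 21 measured genes 0, 0 and 4 rose and 0, 0 and 3 fell, with medians of -0.30, 0.41 and -0.12, the last beside a mean of 0.13 (camera adjusted p = 0.0286 downward, 0.0416 upward and 0.564; adjusted p = 0.454, 0.333 and 0.923 with an estimated correlation). Of these genes 10, 13 and 10 were macrophage-rich, and without them the camera adjusted p was 0.000976, 0.644 and 0.00281, each downward. The list of 47 was written after Atp6v1b2 was seen to be lower in all 3 organs, so this may be a chance find and needs other cultures.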
